A study of Homo sapiens with 12 samples.

How the data were processed

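The arrays were Affymetrix 3' expression arrays hybridised with biotin-labelled RNA prepared with the maker's 3' IVT Express kit, per the labels' protocols. The deposited table holds 1 column per array with log2 values, and RMA and the affy package are named in the submitters' processing notes, without versions. RMA corrects background, brings all arrays to 1 distribution by quantile normalization and summarises the probes of a probe set by median polish; that order of steps is general background on the method, and other settings are not given in the sources used here. The log2 values ran from 1.75 to 14.02 and array medians from 4.80 to 4.86. Quantile normalization removes any overall shift between arrays, and an array with much RNA of another tissue lowers its tumour transcripts in exchange. Arrays have no read depth, and the number of patients limits the precision.

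The 54675 probe sets were named through the platform annotation, with symbols looked up by gene identifier in a RefSeq gene table of assembly GRCh38.p14 (41043 found, 0 symbols altered by it). There were 41097 probe sets with 1 symbol, 1801 with several and 11777 with none, and only those with 1 symbol were named. Control probe sets (62), XIST and Y-linked genes were left out, which left 41032 probe sets of 19740 genes. Each gene was represented by its probe set of highest mean over the 12 arrays. The lowest 25% of genes by that mean were left out, leaving 14805. Other probe sets of a gene can differ. They were compared for 161 genes named or considered for naming, MYL9 and ABCC9 not among them. Of these 161, 101 had several probe sets and 18 had at least 1 of opposite sign. For 2 of the 18 (NAGLU and PGF) that probe set had an unadjusted p below 0.05.

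Samples were grouped as pre or post from the labels. The pairing comes from the labels, which give both biopsies of a patient the same number, and the series describes the biopsies as paired, so patient was a fixed block in every main fit. As a check, deviations from the group means correlated between the arrays of a pair at 0.738, 0.775, 0.798, 0.259, 0.648 and 0.556 for pairs A to F. Between a pre-treatment and a post-treatment array of different patients the highest was 0.293, which every pair but D exceeded. The pre-treatment array of pair D reached 0.243 with another patient's post-treatment array, so the check is weak for pair D. The patients are separate donors, so the spread between pairs includes biological variation.

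Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the log2 values, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of gene changes are limma's moderated ones, and means are given with the SD over arrays. Of 30 gene lists fixed in advance, 465 of 494 entries had a probe set of a single gene, and each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move 1 way on balance and compares them with no other genes. With the preset correlation 16 of 30 lists passed, with an estimated correlation 0, and with fry 3 (angiogenic endothelium, macrophages and Notch). Below, a list is said to rise or fall by its mean change where camera called it at the preset correlation. That preset treats members as nearly independent, while the estimated correlation was as high as 0.921 in the liver list. The wording therefore does not mean that the patients agreed in direction, which the sign-flip tests address. When the arrays were regrouped within pairs, 9 of the 32 possible splits, the real one among them, called at least 16 lists, the highest calling 19. List mean changes per patient were tested with exact two-sided sign-flip tests, whose smallest possible p is 0.0312 for 6 pairs and 0.0625 for 5. Adjusted over the 30 lists, no sign-flip p fell below 0.188. The lists covered angiogenic, general, Notch-related and lymphatic endothelium, mural cells, fibroblasts, basement membrane, growth factor ligands, hypoxia, TFE3 fusion and sarcoma genes, lysosome, proliferation, p53 and apoptosis, ERK feedback, endoplasmic reticulum stress, 5 leukocyte classes, interferon, antigen presentation, inflammation, immediate early genes, wound healing, lung, liver, muscle, fat and red cells. Some genes stood in several lists, such as VEGFA, PGF, MRC1 and EGR1.

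The named genes were fixed by rule: the 10 largest rises and 10 largest falls past the threshold with 1 sign in all 6 patients, filled up with the smallest p of that kind and then given as not passing; 12 receptor, vessel and tumour genes whatever their values; and up to 4 members of smallest p from each list described, with members that passed. Because no gene passed, both directions were filled up. TEK, HEYL, MYH11, ACTA2, FCER1G, APLN, APLNR, PGF, CSPG4, MYL9, ABCC9 and the genes that passed without pair D were chosen after their values were seen. Results are also given without pair D, with the liver list mean and with the ACTB 3' minus 5' difference as covariates; the covariates, and further alternatives run without pair D, were chosen after seeing the data. Alternatives set before the data were examined covered the pairing, normalization, the filter on dim genes, the choice of probe set, the variance model, array weights, each patient left out and the set test. For the random block, camera was run on the moderated statistics; for the trend and robust setting, lists were tested with the variance trend alone.

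The procedure was tested on simulated data with 200 changed genes among 14805, on the spread of the real arrays. Noise was drawn independently for each gene and array. Neither correlation between genes nor a single aberrant array was simulated, so recovery may differ on the real arrays. In the simulation of 6 pairs, 7 of 50 genes changed by 0.5, 30 of 50 changed by 1, 48 of 50 changed by 2 and 45 of 50 changed by 3 on the log2 scale were recovered with 12 false calls. For 5 pairs without pair D these were 17, 42, 47 and 50, with 4 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.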

Results

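Gene expression was measured in paired tumour biopsies from 6 patients with metastatic alveolar soft part sarcoma, a highly vascular soft tissue sarcoma driven by a fusion of ASPSCR1 with the transcription factor TFE3. Each patient gave 1 biopsy before treatment with cediranib, an inhibitor of the VEGF receptor tyrosine kinases, and 1 biopsy 3 to 5 days after its start. The 12 arrays therefore form 6 pairs, called A to F here, with 6 pre-treatment and 6 post-treatment arrays. The comparison addresses which transcripts change in the tumour within the first days of VEGF receptor inhibition. Array medians lay between 4.80 and 4.86 on the log2 scale, and precision is limited by the number of patients. The post-treatment array of pair D held high levels of hepatocyte transcripts, described with its values further on, so the main counts are given with and without this pair.

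The mean of the angiogenic endothelium genes was lower after the start of treatment in all 6 patients, as were 15 of the 22 members singly. ANGPT2, the endothelial ligand that destabilises vessels, averaged 9.18 ± 0.60 before and 6.66 ± 0.78 after treatment (SD, n = 6), a 5.73-fold lower level. The VEGF receptor FLT1 went from 9.76 to 7.49, a log2 change of -2.27 ± 0.31 (SE, n = 6), and KDR, the main signalling receptor for VEGF and a direct target of the drug, from 8.67 to 7.42. ESM1, a proteoglycan secreted by endothelial tip cells, had the largest mean change of the list at -3.13 ± 0.49 (SE, n = 6). PLVAP, the diaphragm protein of fenestrated capillaries, changed by -1.44 ± 0.23 and the potassium channel subunit KCNE3 by -1.79 ± 0.24. The fall was steepest in pair D for ESM1 (-5.255), FLT1 (-3.701), ANGPT2 (-3.504) and PLVAP (-2.604). Without pair D these stood at -2.705, -1.985, -2.321 and -1.202. KDR (-0.209) and KCNE3 (-0.79) fell least in pair D, and stood at -1.453 and -1.986 without it.

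Of the 22 members of the angiogenic list, 15 fell when adjusted over the list alone, and 0 passed when adjusted over all 14805 genes tested. ANGPT2 had a limma adjusted p of 0.000312 over the list alone and of 0.210 over all genes. The members that did not pass included APLN at -0.03, its receptor APLNR at 0.12 and PGF, a ligand of FLT1, at 0.06. With 1 patient left out these ranged from -0.10 to 0.07, from -0.09 to 0.26 and from 0.02 to 0.14, and the other probe set of PGF, at a lower mean of 6.29 against 8.58, stood at -0.57 (unadjusted p = 0.0341), so the direction of PGF depends on the probe set. The list mean fell by 0.94 ± 0.25 (SD over 6 patients), with per-patient changes from -1.17 to -0.55 and an exact sign-flip p of 0.0312 (two-sided), the smallest value 6 pairs allow. By camera the list fell relative to all other genes (adjusted p = 1.26e-15 over 30 lists). The adjusted p = 0.126 with an estimated correlation between members, so the camera call rests on the preset one.

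**Figure D1:**
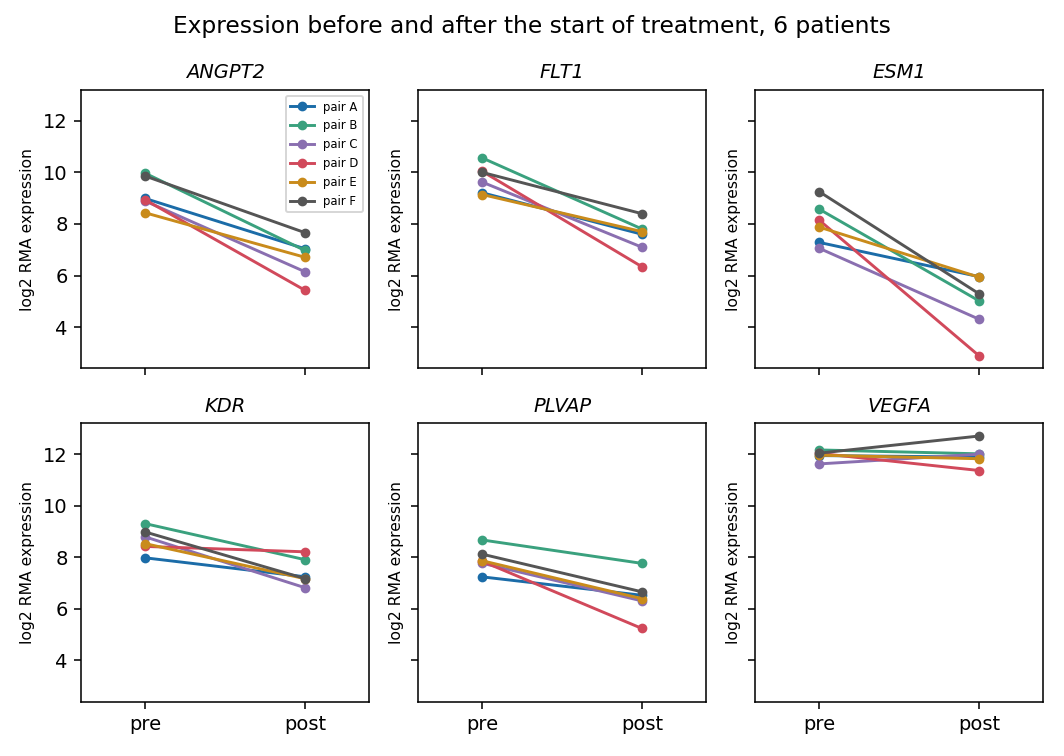
Log2 RMA expression (vertical axis) of ANGPT2, FLT1, ESM1, KDR, PLVAP and VEGFA on the pre-treatment and post-treatment arrays (horizontal axis), with 1 line per patient. The lines of the first 5 genes go down in all 6 patients, while VEGFA averaged 11.96 on both sides and was higher after treatment in 2 of 6.

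Markers carried by endothelial cells in general were also lower on average, but by less. SOX18, a transcription factor of vascular development, changed by -0.44 ± 0.08 (SE, n = 6), from a low mean of 4.64 that lay below every array median. The adrenomedullin receptor CALCRL changed by -1.34 ± 0.25, the endothelial adhesion molecule ESAM by -0.74 ± 0.16 and ECSCR by -0.66 ± 0.16. The angiopoietin receptor TEK moved the other way and was higher in 6 of 6 patients, by 0.62 ± 0.18. Over the 25 pan-endothelial members, 7 fell and 1 rose (TEK) when adjusted over the list alone, and 0 passed over all genes. The list fell by 0.40 ± 0.41 (SD, n = 6) in the camera test (adjusted p = 7.17e-07; adjusted p = 0.456 with an estimated correlation), and 5 of 6 patients were lower (exact sign-flip p = 0.0938). TEK was singled out after its values were seen.

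The angiogenic list fell further than the pan-endothelial list in each patient. The difference between their mean changes was -0.54 ± 0.16 (SE, n = 6), lay below 0 in 6 of 6 patients and ranged from -1.25 in pair D to -0.19 in pair F, with an exact two-sided sign-flip p of 0.0312. Without pair D it was -0.40, below 0 in all 5 remaining patients, where 5 pairs cannot give a p below 0.0625. With probe sets ending in _x_at or _s_at left out it was -0.33, and the exact sign-flip p of 0.0625 no longer passed. The change of the ACTB 3' minus 5' control probe difference, a sign of RNA integrity, was 0.46 in pair C, 0.59 in pair E and 0.66 in pair F, and between -0.01 and 0.06 in the other 3 pairs. With this difference as a covariate, chosen after seeing the data, the pan-endothelial change was -0.11 and no longer passed (camera adjusted p = 0.225).

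The mean of the genes of Notch signalling in endothelium was also lower after the start of treatment in all 6 patients, as were 5 of the 12 members singly. EFNB2, the ephrin of arterial endothelium, changed by -1.05 ± 0.15 (SE, n = 6), the Notch feedback gene NRARP by -0.84 ± 0.16 and the endothelial receptor NOTCH4 by -0.69 ± 0.13. These 3 of the 12 members fell when adjusted over the list alone, and 0 over all genes. The list fell by 0.48 ± 0.27 (SD, n = 6), with 6 of 6 patients lower and a camera adjusted p of 3.62e-05. It had an adjusted p = 0.316 with an estimated correlation.

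Mural cell genes, expressed by the pericytes and smooth muscle cells around vessels, split in direction. The pericyte genes RGS5 and CSPG4 changed by -1.09 ± 0.26 and -0.73 ± 0.18 (SE, n = 6), COX4I2 by -0.52 ± 0.11 and HEYL by -0.93 ± 0.29, each lower in 6 of 6 patients. The contractile genes TAGLN and CNN1 were higher in 6 of 6 patients, by 1.18 ± 0.22 and 0.57 ± 0.11, and MYH11 in 5 of 6, by 0.79 ± 0.25, with -0.31 in pair D. ACTA2, the smooth muscle actin gene, stood at 0.23 ± 0.17, higher in 4 of 6 without passing (0.13 without pair A and 0.36 without pair F). Of the 17 members tested, 7 fell and 3 rose when adjusted over the list alone, and 0 passed over all genes; with the ACTB difference as a covariate 0 fell and 1 rose. Under it the 3 went from a mean of 0.85 to 0.78 and the 7 from -0.84 to -0.66, while the mean SE of their changes grew from 0.19 to 0.27 and from 0.24 to 0.35, and members at an unadjusted p below 0.05 went from 3 to 4 higher (2 of the 3 among them) and from 7 to 1 lower. The remaining higher members were not contractile genes: ABCC9 at 0.58 with the covariate (-0.10 without) and PDGFRB at 0.52. The contractile gene MYL9 went against the split without passing, at -0.509 ± 0.449, and at -0.935 with the covariate. The list as a whole did not pass (mean change -0.25 ± 0.37, SD, n = 6; camera adjusted p = 0.133). PDGFRB, a receptor of pericytes and fibroblasts, stood at -0.06 ± 0.24, and between -0.25 and 0.10 with 1 patient left out.

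Basement membrane genes fell as a list by 0.26 ± 0.17 (SD, n = 6), with 6 of 6 patients lower and a camera adjusted p of 0.0103. The adjusted p = 0.395 with an estimated correlation, and without pair E the camera adjusted p was 0.0692. No member passed over the list alone; the laminin chains LAMB1 and LAMC1 stood at -0.56 ± 0.16 and -0.43 ± 0.14 (SE, n = 6). The ligands of the VEGF, PDGF and FGF families did not pass as a list (mean change -0.25, and -0.115 without pair D; camera adjusted p = 0.187), and PDGFD stood lowest at -1.08 ± 0.29. VEGFA itself stood at 0.00 ± 0.17, and between -0.13 and 0.14 with 1 patient left out. Among the other receptors that cediranib is known to reach, FLT4 stood at -0.25 ± 0.12, KIT at -0.40 ± 0.25 and PDGFRA at 1.51 ± 0.57, the last higher in 6 of 6 patients without passing adjustment (limma adjusted p = 0.616). The PDGFRA change was 4.28 in pair D, and 0.96 on average without it; its other 3 probe sets, all of lower mean, stood at 0.69, -0.03 and -0.05. KIT stood at -0.22 without pair B.

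No gene passed the threshold over all genes in either direction. Besides ANGPT2, FLT1, KCNE3 and EFNB2, the 10 decreases of smallest p that were shared by all 6 patients held the proton-sensing receptor GPR4 (-1.01 ± 0.12, SE, n = 6), the neuroserpin gene SERPINI1 (-1.85 ± 0.24), the integrin chain ITGA8 (-2.09 ± 0.28), the ERK inhibitor SPRY4 (-0.99 ± 0.14), the transcription factor SOX11 (-1.68 ± 0.25) and the semaphorin SEMA3F (-1.18 ± 0.17). The 10 increases were CYP26B1, which degrades retinoic acid, at 1.38 ± 0.24, the haemoglobin scavenger receptor CD163 at 0.93 ± 0.16, the complement receptor C3AR1 at 0.68 ± 0.12, the chemokine receptor CCR1 at 0.91 ± 0.16, the monocyte chemokine CCL2 at 1.74 ± 0.31, TAGLN, CNN1, the interferon-induced IFITM1 at 0.72 ± 0.14, the transcriptional inhibitor ID4 at 0.97 ± 0.20 and the adhesion molecule VCAM1 at 0.58 ± 0.12. These 20 genes had limma adjusted p values between 0.210 and 0.370, so they are given as not passing.

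With all 6 pairs, 0 of 14805 genes passed an adjusted p of 0.05 in limma, and 1061 had an unadjusted p below 0.05 (468 higher and 593 lower), where 740 are expected by chance. Changes of 1 sign in all 6 patients were seen in 480 genes upward and 592 downward, 7.20% of genes against 3.12% by chance. Without pair D, 17 genes passed and all 17 were lower; on these 5 pairs 0 passed with the ACTB or the liver covariate and 2 with no block. They were ANGPT2, ITGA8, MMP9, KCNE3, ACKR3, CA2, FLT1, NID2, EFNB2, PLVAP, TNFAIP8L1, FOLH1B, GPR4, TMEM204, SERPINI1, KDR and KCNN3, of which 6 belong to the angiogenic list. In these 5 patients ANGPT2 changed by -2.32 ± 0.19 (SE, n = 5), ITGA8 by -2.34 ± 0.20, the scavenging chemokine receptor ACKR3 by -1.45 and the matrix protease MMP9 by -2.12. Leaving out each patient was planned, while setting pair D apart was chosen after seeing the data, and the count dropped to between 0 and 3 when any further pair was left out.

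The mean of the macrophage markers was higher after the start of treatment in all 6 patients, as were 6 of the 16 members singly. CD163 had a limma adjusted p of 0.0115 over the list alone, the complement receptor VSIG4 changed by 0.56 ± 0.12 (SE, n = 6), the integrin chain ITGAM by 0.52 ± 0.12 and the signalling adaptors TYROBP and FCER1G by 0.43 ± 0.12 and 0.55 ± 0.15. These 5 of the 16 members tested rose when adjusted over the list alone, and 0 over all genes. The list rose by 0.36 ± 0.15 (SD, n = 6; camera adjusted p = 1.99e-10; adjusted p = 0.179 with an estimated correlation), and its exact sign-flip p was 0.0312.

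Inflammation genes rose as a list by 0.62 ± 0.64 (SD, n = 6, exact sign-flip p = 0.0625; camera adjusted p = 4.77e-05; adjusted p = 0.456 with an estimated correlation), and by 0.39 without pair F. CCL2 and VCAM1 rose when adjusted over the list alone, and 0 of the 16 members passed over all genes. The interleukin 1 receptor antagonist gene IL1RN stood at 1.86 ± 0.58 (SE, n = 6), higher in 6 of 6 patients without passing. Its change was 4.61 in pair D and 3.23 in pair F, and 1.31 on average without pair D. Neutrophil markers rose by 0.30 ± 0.37 (SD, n = 6, exact sign-flip p = 0.125; camera adjusted p = 0.00847; adjusted p = 0.456 with an estimated correlation), with the formyl peptide receptor FPR1 passing over the list alone at 0.85 ± 0.19 and S100A9 at 0.91 ± 0.34 not passing (2.67 in pair D, and 0.56 on average without it). Without pair D the neutrophil list stood at 0.18 with a camera adjusted p of 0.0869. T and NK cell markers did not pass (mean change -0.14 ± 0.49, SD, n = 6; camera adjusted p = 0.661); 4 of 6 patients were higher, pair D stood at -1.03, and the mean without it was 0.035.

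The interferon list rose by 0.39 ± 0.84 (SD, n = 6; camera adjusted p = 0.000350; adjusted p = 0.536 with an estimated correlation), with 3 of 6 patients higher (exact sign-flip p = 0.406). It had a mean of 0.125 and a camera adjusted p of 0.0581 without pair C. IRF7, which controls type I interferon genes, stood at 0.76 ± 0.28 and no member passed over the list alone. Plasma and B cell markers rose by 0.21 (exact sign-flip p = 0.375, camera adjusted p = 0.0443; adjusted p = 0.456 with an estimated correlation), and did not pass without pair E (mean 0.054, camera adjusted p = 0.191). Mast cell markers (-0.11), antigen presentation genes (-0.09) and lymphatic endothelial markers (0.40) did not pass, with camera adjusted p values of 0.555, 0.276 and 0.112, and stood at 0.19, 0.03 and 0.005 without pair D. The ACTB 3' minus 5' difference moved with 3 of the pairs, as given above, and with it as a covariate the inflammation and interferon lists no longer passed (camera adjusted p = 0.0803 and 0.135).

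Feedback genes of ERK signalling fell as a list by 0.29 ± 0.45 (SD, n = 6, exact sign-flip p = 0.0625; camera adjusted p = 0.0101; adjusted p = 0.536 with an estimated correlation). SPRY4 and SPRY1, inhibitors of receptor tyrosine kinase signalling, fell when adjusted over the list alone, SPRY1 by 0.77 ± 0.15 (SE, n = 6), and 0 of the 13 members passed over all genes. The ERK phosphatase DUSP6 stood at -0.39 ± 0.12, lower in 6 of 6 patients. EGR1 of the same list stood the other way, at 0.474 ± 0.185, higher in 5 of 6 patients without passing. Without pair D, whose list change was -1.18, the mean was -0.11 and the camera adjusted p 0.1.

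Hypoxia-inducible genes rose as a list by 0.46 ± 0.65 (SD, n = 6; camera adjusted p = 9.31e-07; adjusted p = 0.478 with an estimated correlation), with 5 of 6 patients higher (exact sign-flip p = 0.0625). The change was 1.72 in pair F, and 0.21 on average without it. None of the 26 members passed over the list alone or over all genes. ANKRD37 and the mitophagy gene BNIP3, both HIF targets, stood at 0.95 ± 0.22 and 1.31 ± 0.37 (SE, n = 6) and were higher in 6 of 6 patients. The BNIP3 change was 2.65 in pair D and 2.52 in pair F, and 1.04 on average without pair D. With the ACTB difference as a covariate the list no longer passed (camera adjusted p = 0.208).

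Proliferation genes fell as a list by 0.28 ± 0.57 (SD, n = 6; camera adjusted p = 0.00125; adjusted p = 0.580 with an estimated correlation), with changes of -1.12 in pair E and -0.84 in pair F and 3 of 6 patients lower (exact sign-flip p = 0.375). No member passed over the list alone, MCM4 of the replicative helicase standing at -0.47 ± 0.18 (SE, n = 6). The call was lost without pair E (mean -0.108, camera adjusted p = 0.189), and with the ACTB difference as a covariate the mean turned to 0.16.

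The mean of the tumour's own genes moved by no more than 0.05 on the log2 scale in 5 of the pairs. The alveolar soft part sarcoma list, which holds targets and partners of the TFE3 fusion, changed by -0.43 ± 1.04 (SD, n = 6; camera adjusted p = 0.133), with -2.56 in pair D and between -0.05 and 0.01 elsewhere. TFE3 stood at -0.01 ± 0.13 (SE, n = 6) and the receptor MET, a target of the fusion, at -0.09 ± 0.12, with ranges of -0.06 to 0.13 and -0.19 to -0.02 when 1 patient was left out. Lysosomal genes (-0.17), p53 target and apoptosis genes (-0.28), endoplasmic reticulum stress genes (0.08) and immediate early genes (0.06, with a median of 0.00 of the other sign) did not pass, with camera adjusted p values of 0.0808, 0.112, 0.104 and 0.222. Without pair F, which stood at 0.62 and 0.567, the endoplasmic reticulum stress and immediate early means turned to -0.033 and -0.041. Without pair D the lysosomal mean was -0.025 and the p53 mean -0.04, and immediate early genes passed at 0.147 (camera adjusted p = 0.0231; adjusted p = 0.566 with an estimated correlation).

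The liver list marked pair D. Its mean was 8.93 on the pre-treatment and 13.09 on the post-treatment array of this pair, against 4.20 to 6.15 on the other 10 arrays, and the fibrinogen gene FGA changed by 4.37 in it. Of the sarcoma list, the steroid hydroxylase gene CYP17A1 and the synaptic vesicle gene SV2B changed by -8.18 and -8.27 in pair D. The correlation across probe sets of its post-treatment array with its own pre-treatment array was 0.901, against 0.980 to 0.997 in the other pairs. Across the 6 patients the liver list rose by 0.79 ± 1.66 (SD, n = 6, exact sign-flip p = 0.0938; camera adjusted p = 0.000350; adjusted p = 0.536 with an estimated correlation) and by 0.11 without pair D.

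**Figure D2:**
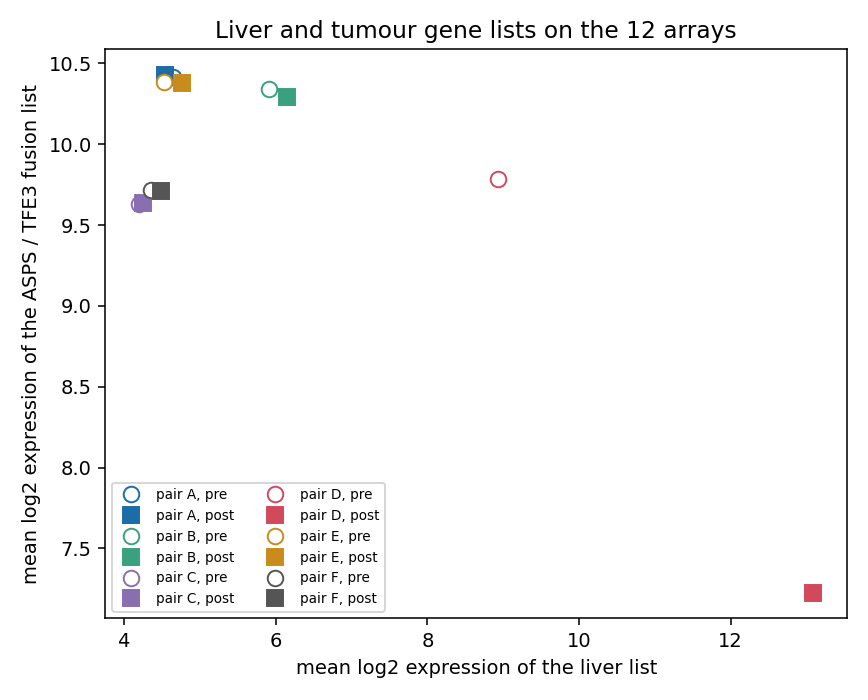
Mean log2 expression of the liver list (horizontal axis) against that of the alveolar soft part sarcoma list (vertical axis) on the 12 arrays, with open circles for pre-treatment, filled squares for post-treatment arrays and 1 colour per pair. The post-treatment array of pair D lies at 13.09 and 7.23, apart from all others.

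Of the lists for other tissue, fibroblast genes rose by 0.40 ± 0.68 (SD, n = 6, exact sign-flip p = 0.344; camera adjusted p = 0.00903; adjusted p = 0.514 with an estimated correlation), with 1.295 in pair D and 1.22 in pair F and a mean of 0.22 without pair D, and did not pass without pair F (mean 0.235, camera adjusted p = 0.189). Fibronectin, FN1, stood at 0.43 ± 0.13 (SE, n = 6) and no member passed over the list alone. Wound healing and TGF-beta genes rose by 0.36 ± 0.50 (SD, n = 6, exact sign-flip p = 0.156; camera adjusted p = 0.0103; adjusted p = 0.478 with an estimated correlation), and not without pair F (mean 0.198, camera adjusted p = 0.142). Their members INHBA, at 1.39 ± 0.41 (SE, n = 6), and TNC, at a 2.82-fold higher mean level, were each higher in 6 of 6 patients without passing, and MMP9 of the same list stood at -1.55 ± 0.50. The INHBA change was 3.22 in pair D, and 1.02 on average without it. TNC changed by 3.91 in pair D and 2.75 in pair F, and without pair D its mean level was 2.02-fold higher. MMP9 changed by 1.29 in pair D. Skeletal muscle genes rose by 0.20 (exact sign-flip p = 0.219, camera adjusted p = 0.00847; adjusted p = 0.395 with an estimated correlation), by 0.12 without pair F and by 0.33 without pair D. With the ACTB difference as a covariate the basement membrane, wound healing, skeletal muscle and B cell lists did not pass (camera adjusted p = 0.152, 0.721, 0.525 and 0.305). Lung epithelium (0.07), adipocyte (0.19) and red blood cell genes (0.06) did not pass, with camera adjusted p values of 0.0984, 0.306 and 0.0808; without pair D the adipocyte mean was -0.015 and the red blood cell mean -0.04.

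**Figure D3:**
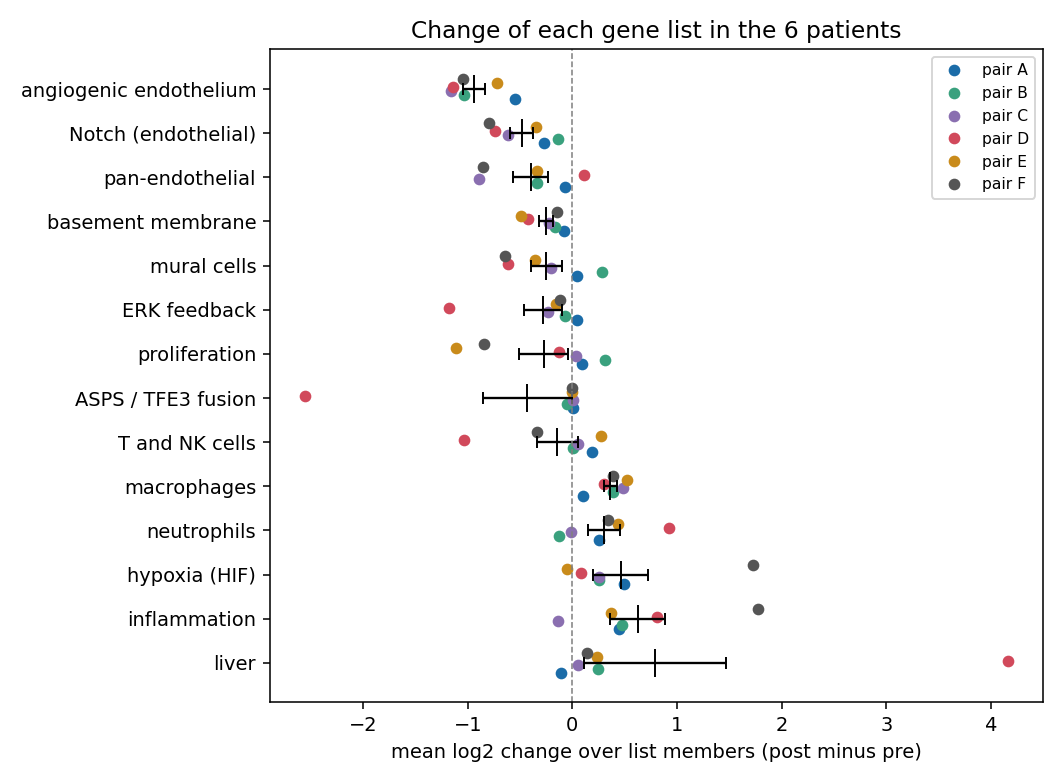
Mean log2 change over the members of 14 gene lists (horizontal axis, post minus pre) for each of the 6 patients (points, 1 colour per pair), with the mean (black tick) and its SE over patients (bar). The angiogenic list lies below 0 in all 6 patients (-1.17 to -0.55), the macrophage list above 0 in all 6, and the liver and sarcoma lists are set apart by pair D alone (4.16 and -2.56).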

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

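Among 321 groups of 6 values looked at (30 lists and 77 named genes, before, after and as change), 40 held a patient whose gap to the nearest other patient as a share of the group's range exceeded Dixon's critical value. Chance alone gives about 1 in 20, or 16 here, and 30 of the 40 lay in pair D. Some of the 77 genes were named because they passed without pair D, which raises the share of this pair. The tests of explanations in this part were chosen after the result was seen.

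Pair D stood apart first by its liver list, at 8.93 before and 13.09 after treatment and with a change of 4.16, and by FGA with a change of 4.37. The level of FGA was also high in pair B, at 10.09 before and 11.12 after treatment, where the liver list stood at 5.91 and 6.15. Its sarcoma list was 7.23 after treatment, with a change of -2.56, against 9.64 to 10.43 on the other post-treatment arrays, with TFE3 at a change of -0.68. CYP17A1 fell to 4.28 (change -8.18) and SV2B to 3.90 (change -8.27), where the other post-treatment arrays lay at 11.09 or higher for both. A candidate explanation is liver tissue in place of tumour: the liver list of this array lay 4.16 above the highest of the other 11 and its sarcoma list differed from the lowest of them by -2.40, as liver tissue would give. These lists are also what set the array apart, so the values describe it and are no separate test. Degraded RNA is argued against, since the ACTB 3' minus 5' difference of 0.97 lay within the range of the others, up to 1.65. Its GAPDH 3' minus 5' difference of 0.31 was shared by its own pre-treatment array and lay above the 0.16 reached by the other 10, but that pre-treatment array, with an ACTB difference of 0.96, had a median correlation of 0.964 with other patients' arrays, against 0.881 after treatment. Whether the array belongs to another patient cannot be told apart from this: its deviations correlated at 0.259 with its own pre-treatment array and at most at 0.009 with another patient's, but its own pre-treatment array also held liver transcripts.

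Further values of pair D were the lymphatic list at 7.99 after treatment (change 2.35), the Notch list at 6.99 after treatment, the p53 list at 7.93 (change -1.47), and list changes of -0.90 for growth factor ligands, -0.87 for lysosome, -1.18 for ERK feedback and -1.57 for mast cells. Its adipocyte list was 4.96 before treatment. Among genes, KCNE3 was 8.42 and TNFAIP8L1 9.03 after treatment, and changes were 1.29 for MMP9, 1.62 for CA2, 0.97 for NID2, 1.63 for TNFAIP8L1, -1.62 for KCNN3, -2.71 for PDGFD and -1.14 for LAMC1. MMP9, CA2, NID2 and TNFAIP8L1 are among the 17 genes that passed without this pair, and in each of these 4 genes pair D was the only patient with a change above 0. Genes that pass only without a pair are apt to differ in it, so this follows in part from their choice.

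In pair F the hypoxia list changed by 1.72 and endoplasmic reticulum stress genes by 0.62. ANKRD37 was 9.31 after treatment with a change of 2.13 in this pair, and before treatment CNN1 was 6.70, CSPG4 7.47 and ACTA2 12.13. In pair E the proliferation list was 8.09 before treatment, against 6.34 to 6.98 in the others. In pair C, FPR1 was 8.97 and S100A9 10.54 before treatment, where the others lay at 7.08 or lower and 7.84 or lower.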

How the results depend on the processing

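The liver and ACTB covariates and all further settings run without pair D were chosen after seeing the data. The count of 0 genes with 6 pairs became 14 (0 higher, 14 lower) with patient as a random replicate block and 24 (3 higher, 21 lower) with arrays weighted, where pair D had a weight of 0.124; leaving out each patient gave 0 to 17, all lower, and only pair D's omission gave more than 0. Ignoring the pairing (no replicate block) gave 0, as did every other setting. Genes at an unadjusted p below 0.05 numbered 370 without the block, 627 with a stricter filter on dim genes, 463 with the ACTB covariate and 588 without pair F, against 1061. The angiogenic list kept its direction and passed everywhere (change -1.02 to -0.90 with a patient left out) except with an estimated correlation (adjusted p = 0.126). The pan-endothelial list did not pass with the ACTB covariate (adjusted p = 0.225), an estimated correlation (0.456) or fry (0.276). The angiogenic minus pan-endothelial change was -0.33 without _x_at and _s_at probe sets and -0.61 to -0.40 with a patient left out, where 5 pairs cannot pass. The 17 genes without pair D became 2 with no replicate block, 38 with the random block, 3 after quantile normalization again, 5 with no filter, 2 with means over probe sets, 0 with either covariate and 0 to 3 with a further patient left out; at an adjusted p of 0.10 they were 36. With a patient left out, the uncalled mural, ligand, sarcoma, lysosome, p53, endoplasmic reticulum stress, antigen presentation, immediate early and red blood cell lists each gained a call in at least 1 case. The proliferation list turned to a rise with the ACTB covariate (adjusted p = 0.0400). Of 595 list results over all settings, 505 kept direction and side of the threshold, 67 lost and 22 gained a call; 24 uncalled values had the other sign. Of 2801 gene results, 47 gained a call, 0 called values turned and 56 uncalled values had the other sign. Beyond smaller sample numbers, the causes were not tested.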

Other observations

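The family searches, the mural comparison and the tests on the angiogenic list were chosen after the results were seen, and the splits of the arrays were planned before. Among 255 families of genes sharing a symbol root, 11 passed camera with the preset correlation and none with an estimated one (adjusted p = 0.882 for each). The clustered protocadherins PCDHB, neuronal adhesion genes, were lower on average by 0.32 ± 0.19 (SD, n = 6) over 12 genes, in 6 of 6 patients (camera adjusted p = 0.000439, exact sign-flip p = 0.0312). The CCL chemokines, which attract leukocytes, were higher by 0.53 ± 0.36 (SD, n = 6) over 14 genes in 6 of 6 patients (camera adjusted p = 0.00376), and CCL2 had an unadjusted limma p of 0.000799.

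The fall of the angiogenic list in all 6 patients may reflect loss of VEGF-dependent expression rather than of vessels, a hypothesis that was not tested. An even loss of endothelial cells as the whole cause is argued against by the list's further fall than the pan-endothelial list (-0.542 ± 0.159, SE, n = 6, exact sign-flip p = 0.0312). This difference missed the threshold without _x_at and _s_at probe sets. It was largest in pair D (-1.249), where the pan-endothelial list changed by 0.11. Without pair D it was -0.40, with an exact sign-flip p of 0.0625, the smallest that 5 pairs allow. The lists also differed in level before treatment (8.91 and 7.44), and whether an even loss would move both equally was not tested. Loss of mainly those endothelial cells that carry the angiogenic genes would also give the further fall. The comparison therefore cannot part lost cells of that kind from lost expression. Lower RNA integrity and the liver transcripts of pair D as the whole cause are argued against by the list change over patients, -0.931 ± 0.165 at no ACTB change (SE, n = 6, 95% interval -1.39 to -0.472) and -0.901 ± 0.115 without pair D (SE, n = 5, 95% interval -1.22 to -0.581). By camera these passed with the preset correlation (adjusted p = 5.41e-10 and 2.57e-20) and not with an estimated one (adjusted p = 0.707 and 0.236). Effects of time or of a second biopsy stay open, since no untreated pairs were analysed here.

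Of the mural list, 3 members rose and 7 fell when adjusted over the list alone. A change of all mural cells by the same share alone, which would move its members the same way, is argued against by these calls. Most of the calls were lost with the ACTB covariate, as given below. Opposite changes in the amounts of pericytes and smooth muscle cells would also split the members, so the test cannot exclude them. More fibroblast tissue as the whole cause of the higher contractile genes would make their mean change follow that of the fibroblast list over patients. The correlation between them was -0.907 (95% interval -0.99 to -0.359, n = 6), which argues against this cause over the 6 pairs. Without pair D the correlation was -0.847, with an interval of -0.99 to 0.141. That interval reaches above 0, so the other 5 pairs alone do not settle it. Lower RNA integrity as the whole cause stays open: with the ACTB covariate 1 member rose and 0 fell, as the mean changes of the 3 and the 7 shrank (0.85 to 0.78, and -0.84 to -0.66) and their mean SE grew (0.19 to 0.27, and 0.24 to 0.35), with 4 members higher and 1 lower at an unadjusted p below 0.05, against 3 and 7. On a division made after the values were seen, the 6 contractile genes stood at 0.42 (5 of 6 patients higher, exact sign-flip p = 0.0938) and the 11 others at -0.61 (5 of 6 lower, pair B higher, p = 0.0625), and neither part passed by itself. Their difference of 1.03 ± 0.20 (SE, n = 6; 6 of 6 patients, exact sign-flip p = 0.0312) describes that division only. A change of state of mural cells, or smooth muscle from larger vessels, may underlie the pattern and was not tested.

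Splits of the 12 arrays into groups of 6 were fitted with the same block, 100 in all with the real one among them: the 32 that part every pair, of which 31 are not the real one, and 68 drawn from those that part some. Splits that differ only in where whole pairs lie give the same fit, so the 68 held 51 distinct fits and the 100 held 83. All 100 gave at least the real 0 genes, and the highest gave 556. For unadjusted p below 0.05, 17 of 100 splits reached the real 1061, the highest giving 4602, so chance cannot be excluded on this count; of the 32 splits parting every pair only the real one did, the next giving 848. Splits that leave pairs whole rest on fewer pairs, and all 7 that called genes part only 2 pairs. For lists passing camera, 11 of 100 splits reached the real 16 (9 of the 32), with a highest of 19, so chance cannot be excluded for the number of lists. For angiogenic members at an unadjusted p below 0.05, only the real split reached 15 (1 of 100, highest other 14, and 12 among the 32). The 68 that part only some pairs rest on fewer pairs, so only the share of 1 of 32 bears on chance. That is the smallest share these splits can give, and it is not adjusted for the other lists. The list's exact sign-flip p was 0.188 when adjusted over all lists, so chance cannot be excluded for this list. Without pair D, 17 genes stood against a highest of 0 in the other 15 of 16 splits, too few for a share under 0.05 (1 split reached it).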
